A study of Mus musculus with 10 samples.

How the data were processed

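The series measured gene expression by bulk RNA sequencing in the medial prefrontal cortex of 10 mouse libraries. Libraries with the numbers 3, 4, 5, 7 and 9 came from mice given a control adeno-associated virus (AAV), and libraries 13, 14, 15, 17 and 18 from mice given an AAV that overexpressed the microRNA miR-130a-3p. Per the labels' protocols, the tissue was taken as a 1-mm punch, RNA with an integrity number of at least 6.5 was accepted, and stranded libraries were made from poly(A)-selected mRNA by adapter ligation. Per the submitters' processing notes, fastp, HISAT2, RSEM and DESeq2 were used with the genome build GRCm39; the notes used here give no versions and no role for each tool.

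The authors deposited TPM values per gene and library, with gene symbols, biotypes and annotation terms beside them. TPM divides by transcript length and by the library's total, so that every library adds to the same sum and a large change in a few genes shifts all others. TPM keeps no depth, so the number of reads behind a value is unknown and no counting interval was computed. Count models were not used, because the deposited values are TPM and not counts. The 2 columns of group means in the deposited table were the authors' own and were not used here. Columns were assigned to libraries by the sample titles. The labels name mice but do not say how many, so p-values measure the spread between these libraries.

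Values were analysed as log2(TPM + 1), and every fold change is on that scale, which understates the change of weakly expressed genes. Of 78317 genes listed, 15680 with a mean of at least 1 TPM over all 10 libraries were tested. Groups were compared with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3 with the data.table package (version 1.17.8), 5 against 5 libraries, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used, since the labels give no batch. The library numbers run in separate blocks for the groups, so a difference in cage or processing that followed them would coincide with the group. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, and also with a correlation estimated per list and with fry. Camera compares a list with all other genes, while fry asks whether its genes move on balance in 1 direction and makes no comparison with other genes. For each list a score per library was formed as the mean over members of the log2 value minus the gene's mean, and groups were compared with an exact permutation test over all splits of the libraries into 5 and 5, 2-sided, whose smallest possible p is 0.00794. Exact p-values are printed unadjusted unless said otherwise, and counts of lists past that test use Benjamini-Hochberg adjustment over the 29 lists.

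The lists, 29 in all with 527 entries, were fixed before the data were examined, as were the tests, most alternatives and the rule for naming genes. They covered homeostatic microglia, activated microglia, complement and phagocytic receptors, the interferon response, antigen presentation, NF-kB and cytokine genes, T cells, B cells and border myeloid cells, astrocytes, reactive astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, endothelial cells, mural cells and fibroblasts, excitatory neurons, inhibitory neurons, immediate early genes, synapse, monoamine and neuropeptide signalling, the glucocorticoid response, reported miR-130a-3p targets, microRNA machinery, striatum and claustrum, choroid plexus and ependyma, blood, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, the cytosolic ribosome, stress and DNA damage, and sex-linked genes. In these lists 6 genes occur more than once. The genes named were the Mir130a entry, the 12 genes with the largest increase and the 12 with the largest decrease past the threshold (predicted or clone-named models left out), the 3 members of each list with the lowest p, the reported targets past the threshold, and the 2 lowest-p members of up to 5 annotation terms per direction. Some genes that this rule selects are not reported here. Any other gene is said to have been chosen after its values were seen.

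Annotation terms from the deposited table (Gene Ontology and KEGG, 10 to 500 tested genes each) were tested with camera in the same way. Sites for miR-130a-3p were searched as TTGCACT, TGCACTA and, for both together, TTGCACTA in the longest annotated 3′ untranslated region (UTR) of each gene, using GRCm38 with GENCODE M21 transcripts matched by gene identifier. Because that build differs from the GRCm39 of the processing notes, no coordinates are given. Of the genes tested, 13307 had an annotated 3′ UTR. Genes with a site were compared with genes without one in 10 bins of UTR length by a score per library and an exact permutation test, and 50 shuffled heptamers of the same base composition gave the background. The UTR search and the figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

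Alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 TPM, quantile normalization, median-ratio scaling, rescaling without mitochondrially encoded genes, robust variance moderation, array weights, and leaving out each library in turn. Leaving out control libraries 7 and 9 together, rescaling to protein-coding genes outside the mitochondrial genome, bins of UTR length and AT content, and median-ratio scaling of the site comparison were added after the data were seen. The gene test was tested on simulated data of 15680 genes, a small share of them given changes of known size. Of genes changed by 0.5 log2 units 23.9% were called, of those changed by 1 80.6% and of those changed by 2 93.9%. There were 7 unchanged genes called and 0 calls of the wrong sign. Each simulated gene had the same SD in both groups. Power depends on that spread and on how many genes change, so these shares do not give the sensitivity of the real comparison. With nothing changed, 0 genes were called. Of the simulated unchanged lists, 4% had an exact p under 0.05 and 2.5% a camera p under 0.05. Simulated genes varied independently, while the real lists had estimated correlations such as 0.21 for homeostatic microglia and 0.87 for antigen presentation. The camera share therefore does not show how camera at the preset correlation behaves on lists of correlated genes. In simulated data with site genes lowered by 0.1, the site comparison over 13307 genes returned −0.102.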

Results

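Gene expression was measured by poly(A) RNA sequencing in punches of mouse medial prefrontal cortex, a frontal region studied in mood and stress. The design compared 5 libraries from mice given an AAV for overexpression of miR-130a-3p with 5 libraries from mice given a control AAV. It asks which transcripts change when this microRNA is overexpressed in that tissue. The values are deposited TPM, for which the depth of each library is unknown.

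Mir130a (ENSMUSG00000065484), the gene of the overexpressed microRNA, was listed at 0 in all 10 libraries. The table listed 2206 microRNA genes, of which 0 had a value above 0, so these libraries do not measure the overexpression itself. Xist, transcribed from the inactive X chromosome of females, lay between 0 and 0.01 TPM in all 10 libraries, and the Y-linked Ddx3y between 7.39 and 17.2 TPM. Mitochondrially encoded genes took 14.7% ± 1.48 of TPM in control and 18.2% ± 1.96 in miR-130a libraries (SD, n = 5 each; exact permutation p = 0.0397). Pseudogenes took 9.73% ± 0.519 and 10.5% ± 0.498 (SD, n = 5 each; exact permutation p = 0.0397). The 10 most abundant genes took 18.7% ± 1.45 and 21.5% ± 2.20, a difference that did not pass (SD, n = 5 each; exact permutation p = 0.0635). Between 24130 and 26429 genes had a value above 0 per library, without a detectable group difference (exact permutation p = 0.881). Pairwise correlations of log2 values across genes ranged from 0.904 to 0.977, and 0 pairs of libraries were identical. The first principal component held 35% of the variance. All 5 miR-130a libraries scored between 15.1 and 39.6 on it and all 5 controls below 0, with control libraries 7 and 9 farthest out at −46.7 and −62.9. Control library 9 also had the lowest mean correlation with its own group, 0.934.

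The 12 named genes with the largest decrease were all known from myeloid or lymphoid cells or from antigen presentation. Cst7 (ENSMUSG00000068129), a cathepsin inhibitor of activated microglia, fell from 58.7 ± 24.4 to 3.96 ± 2.51 TPM, and Clec7a, a receptor for fungal glucans on myeloid cells, from 41.9 ± 27.6 to 2.76 ± 1.99 TPM (SD, n = 5 each). The chemokine Ccl3 fell from 10.7 ± 5.40 to 0.416 ± 0.416 TPM and the galectin Lgals3 from 26.2 ± 23.8 to 1.97 ± 0.927 TPM. With clone-named models left out, upward changes were smaller: Cort, a neuropeptide of cortical interneurons, rose from 25.2 ± 3.86 to 69.7 ± 20.5 TPM, and Grp, gastrin-releasing peptide, from 14.8 ± 2.75 to 30.1 ± 4.48 TPM. Msmo1 and Hmgcs1, enzymes of cholesterol synthesis, rose from 48.6 ± 5.35 to 110 ± 17.2 TPM and from 106 ± 16.0 to 225 ± 51.8 TPM. In limma these 8 genes had adjusted p-values between 0.000503 and 0.00492.

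Of 15680 genes, 2110 passed an adjusted p of 0.05 in limma, 1767 lower and 343 higher in the miR-130a group. A change of at least 2-fold was found in 503 of the lower and 15 of the higher genes. For 1527 of the 2110, the ranges of the groups did not overlap; such separation occurred in 11.3% of all tested genes, against 0.794% by chance. At an unadjusted p under 0.05 there were 4455 genes. The median log2 fold change of all tested genes was −0.09, and the balance of directions moved with the scaling. Median-ratio scaling, which set that median at 0.01, gave 1198 lower and 866 higher genes, so that 42.0% of calls were higher against 16.3% as deposited. Quantile normalization, with a median of 0.05, gave 1046 lower and 1071 higher, and rescaling to protein-coding genes gave 1411 lower and 563 higher. Rescaling without mitochondrially encoded genes gave 1347 lower and 488 higher. Without control libraries 7 and 9, a choice made after seeing the data, 2442 genes were lower and 361 higher, and 1559 of the 2110 calls remained. The total was 1254 without control library 7, 1279 without miR-130a library 14, 1306 without miR-130a library 13 and 3421 without control library 9.

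**Figure D1:**
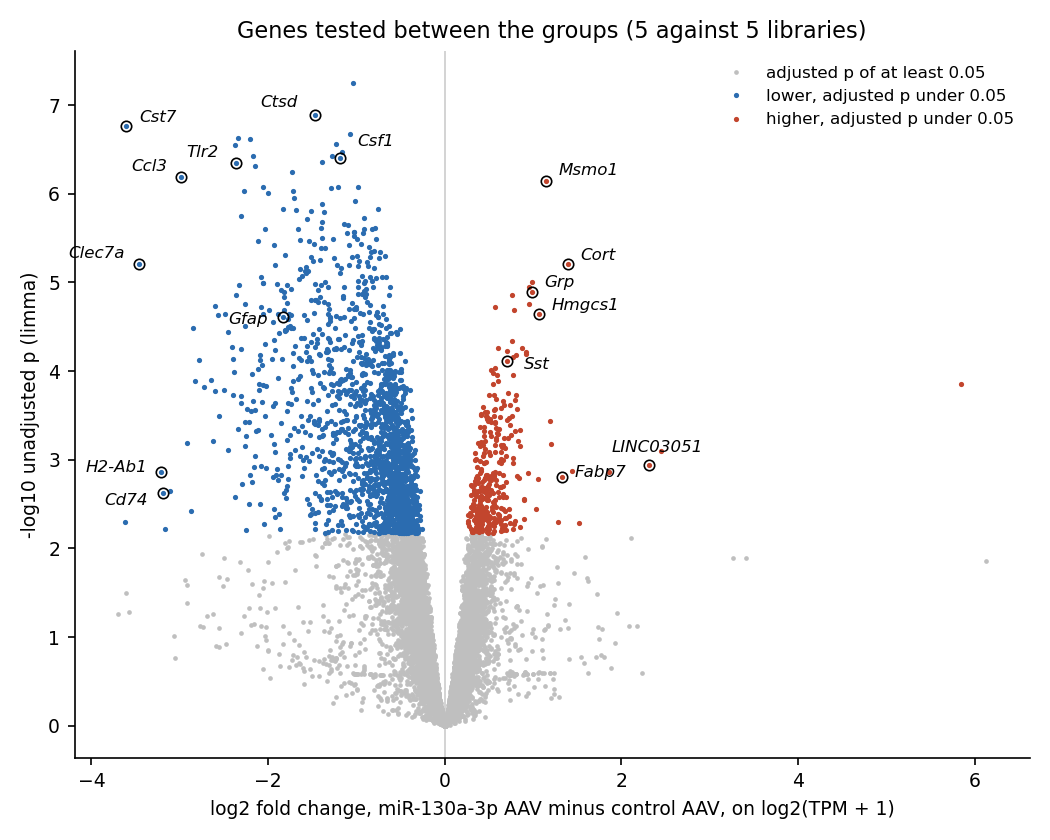
Log2 fold change (miR-130a minus control, on log2(TPM + 1)) on the horizontal axis against −log10 of limma's unadjusted p on the vertical axis, with 1 point per tested gene and genes past an adjusted p of 0.05 in color. Lower genes (1767) outnumber higher genes (343) with TPM as deposited, while median-ratio scaling gave 1198 and 866; the called point farthest to the right is Gm45665, a processed pseudogene singled out after its value was seen.

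Among the 12 genes of largest decrease, the class II molecules H2-Ab1, H2-Aa and H2-Eb1 and their chaperone Cd74, which present antigen to T cells, fell with wide scatter in the controls. H2-Ab1 was at 298 ± 301 TPM in control and 23.4 ± 18.2 TPM in miR-130a libraries, and Cd74 at 870 ± 944 and 75.0 ± 64.1 TPM (SD, n = 5 each). The immunoglobulin segments Igkv6-25 and Ighv1-64 were at 62.3 ± 62.2 and 45.8 ± 82.6 TPM in control and 7.90 ± 15.9 and 0.948 ± 1.30 TPM in miR-130a libraries. Limma adjusted p-values of these 6 genes lay between 0.0185 and 0.0468. All 6 missed the threshold when control libraries 7 and 9 were left out, with adjusted p-values from 0.0553 for H2-Ab1 to 0.102 for H2-Eb1. The log2 fold changes of the class II genes, Cd74 and Ighv1-64 then shrank from between −3.21 and −2.87 to between −2.08 and −1.66, while that of Igkv6-25, highest in control libraries 3 and 5, went from −3.62 to −4.03. These 6 calls were also lost on leaving out single libraries, from 3 of the 10 in turn for H2-Ab1 to 8 for Igkv6-25. Robust variance moderation and testing without a filter ended all 6 as well. The class I gene H2-Q6 fell from 64.0 ± 33.2 to 8.40 ± 5.90 TPM (log2 fold change −2.85, limma adjusted p = 0.00246) and Ly6c2, a surface antigen of monocytes and lymphocytes, from 52.2 ± 45.8 to 5.16 ± 3.71 TPM (−2.91, 0.0119). Class I, class II, immunoglobulin and Ly6c genes have near-identical relatives, so the split of their reads between copies is uncertain. Among the largest increases, Fabp7, a fatty acid binding protein of radial glia and astrocytes, rose from 42.9 ± 17.7 to 110 ± 56.3 TPM. Spink8, a serine protease inhibitor gene, rose from 1.24 ± 0.631 to 4.12 ± 1.66 TPM and Pter, a phosphotriesterase-related gene, from 46.4 ± 5.33 to 91.7 ± 17.5 TPM. LINC03051 rose from 2.84 ± 3.88 to 12.5 ± 3.69 TPM with overlapping ranges (2.32, 0.0165). The calls of Ucma (2.56 ± 1.98 to 9.20 ± 4.51 TPM) and Fcor (8.90 ± 4.34 to 18.2 ± 2.78 TPM) were lost on leaving out single libraries, 7 and 3 of the 10 in turn, with limma adjusted p-values of up to 0.104 and 0.0588.

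Genes typical of resting microglia, the resident macrophages of the brain, were lower in the miR-130a group. Csf1r, the receptor that microglia need for survival, fell from 147 ± 23.4 to 55.7 ± 13.1 TPM. Laptm5, a lysosomal membrane protein of blood-lineage cells, fell from 114 ± 24.6 to 40.6 ± 10.4 TPM (SD, n = 5 each). Of 20 homeostatic microglial genes, 16 were lower and 0 higher, and 4 did not pass; 18 passed adjusted over the list alone. Their median log2 fold change was −0.96, or −0.87 relative to all genes (limma camera adjusted p = 4.08e-12; adjusted p = 0.0763 with an estimated correlation). The microglial receptor P2ry12, chosen after its values were seen, was at 42.5 ± 9.15 and 36.8 ± 7.42 TPM and did not pass (limma adjusted p = 0.485).

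Genes induced in activated microglia were also lower. The lysosomal proteases Ctsd and Ctsb fell from 1103 ± 148 to 399 ± 67.2 TPM and from 896 ± 109 to 424 ± 29.9 TPM (SD, n = 5 each). Together with Cst7, 17 of 22 members were lower, 0 were higher and 5 did not pass; 18 passed adjusted over the list alone. The median log2 fold change relative to all genes was −1.21 (limma camera adjusted p = 4.6e-13; adjusted p = 0.222 with an estimated correlation). Of the complement and phagocytic receptor genes, C1qc, a chain of the initiating complement component, fell from 408 ± 128 to 98.6 ± 21.0 TPM, the Toll-like receptor Tlr2 from 12.7 ± 5.32 to 1.54 ± 0.372 TPM, and Cd180, a Toll-like receptor homolog, from 20.7 ± 6.71 to 3.49 ± 1.34 TPM. In this list 19 of 20 tested members were lower and 0 higher, 1 did not pass, and 20 passed adjusted over the list alone. Its median relative to all genes was −1.53 (limma camera adjusted p = 5.85e-15; adjusted p = 0.222 with an estimated correlation). C4b, a member of that list, has a near-identical paralog and its reads may be shared.

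For these 3 lists every miR-130a library scored below every control library (score differences −0.85, −1.43 and −1.54; exact permutation p = 0.00794 each, the smallest the splits can give). Control libraries 7 and 9 had the highest activated microglial scores, 0.93 and 1.39, where the other controls lay between 0.25 and 0.63. Without them, 15 homeostatic, 16 activated and 18 complement genes were lower.

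**Figure D2:**
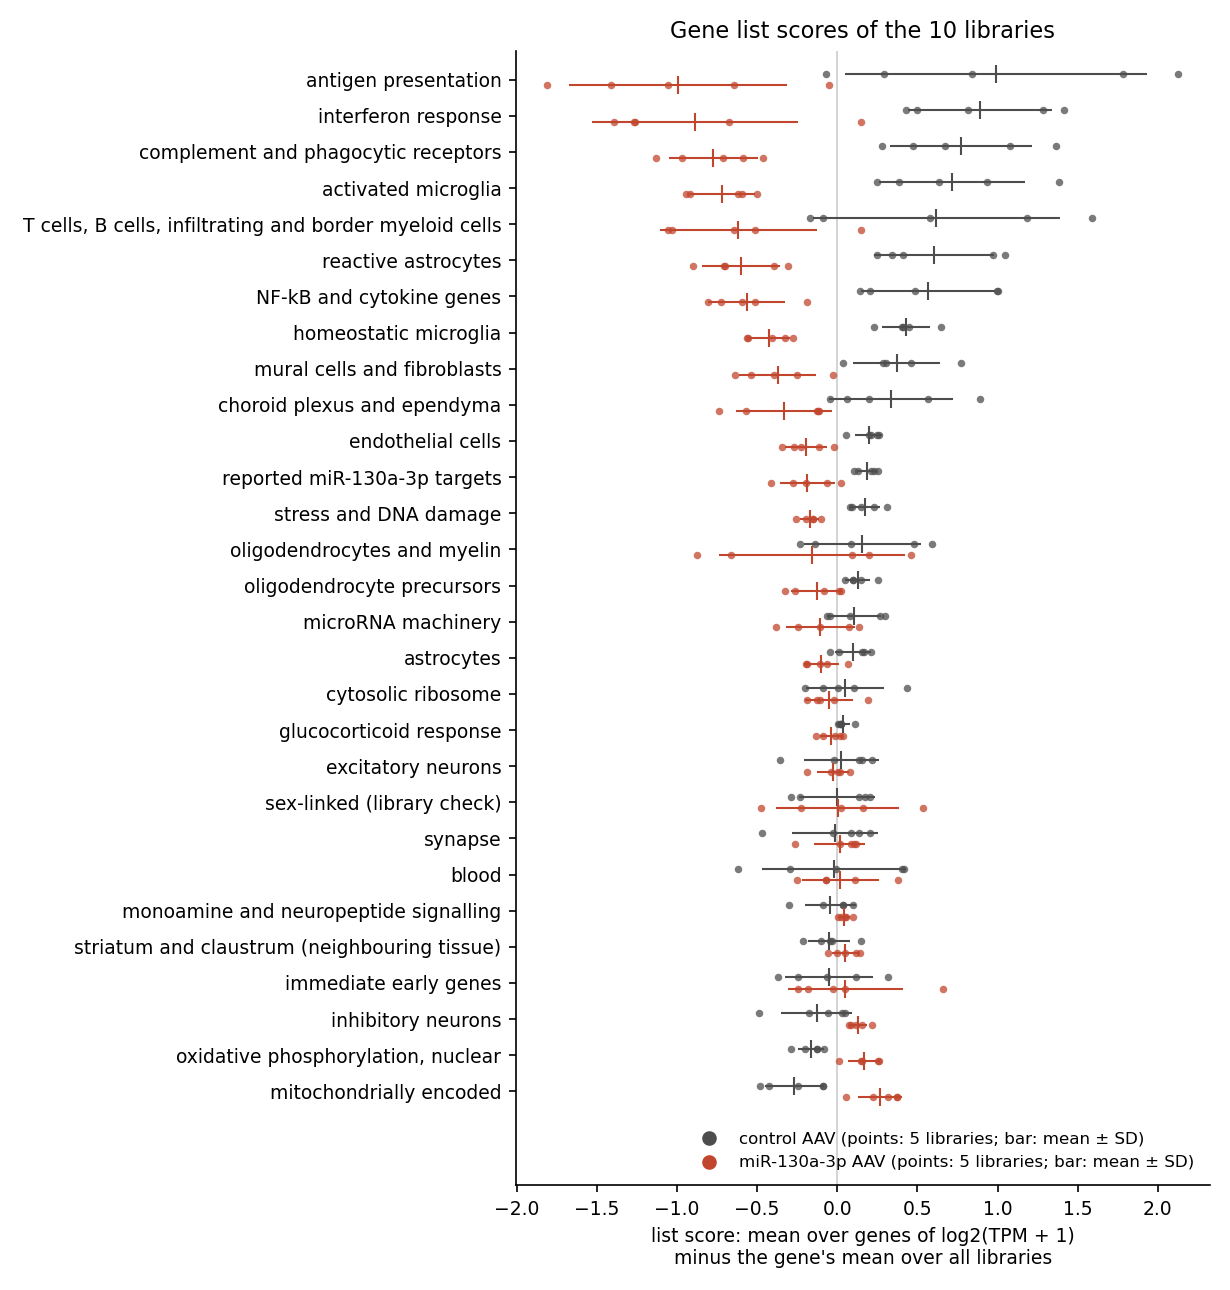
Scores per library (mean log2(TPM + 1) of a list's members minus each gene's mean over the 10 libraries) for the 29 fixed gene lists, with a point per library and bars for mean ± SD (n = 5). The homeostatic microglial scores of the miR-130a libraries lay between −0.57 and −0.28 and those of the controls between 0.23 and 0.65.

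Genes of the interferon response fell almost throughout the list. Lgals3bp, a secreted glycoprotein induced by interferon, fell from 244 ± 44.6 to 53.5 ± 16.2 TPM, Oas1a, an antiviral oligoadenylate synthetase, from 27.0 ± 6.96 to 4.93 ± 2.55 TPM, and Rigi, a cytosolic RNA sensor, from 12.7 ± 2.41 to 4.54 ± 1.57 TPM (SD, n = 5 each). Of 30 members, 29 were lower, 0 were higher and 1 did not pass; 30 passed adjusted over the list alone. Relative to all genes, the median was −1.68 (limma camera adjusted p = 2.3e-18; adjusted p = 0.223 with an estimated correlation). Of the NF-kB and cytokine genes, the tumor necrosis factor receptors Tnfrsf1a and Tnfrsf1b fell from 28.0 ± 6.32 to 11.1 ± 1.75 TPM and from 10.4 ± 3.93 to 2.68 ± 0.446 TPM. In that list 13 of 18 tested members were lower and 1 higher, 4 did not pass, and 15 passed adjusted over the list alone. The median relative to all genes was −0.92 (limma camera adjusted p = 1.63e-07; adjusted p = 0.267 with an estimated correlation). Both lists had scores without overlap between the groups (differences −1.78 and −1.13; exact permutation p = 0.00794 each, the smallest possible). Without control libraries 7 and 9, whose interferon scores were 1.42 and 1.29 against 0.43 to 0.82 in the other controls, 22 interferon and 11 NF-kB and cytokine genes were lower.

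Antigen presentation genes were lower as well. Tapbp, which loads peptides onto class I molecules, fell from 83.7 ± 26.4 to 29.2 ± 6.0 TPM, and the class I heavy chains H2-K1 and H2-D1, whose reads may be shared with related genes, fell from 718 ± 356 to 136 ± 74.7 TPM and from 739 ± 331 to 153 ± 75.7 TPM (SD, n = 5 each). Of 16 members, 13 were lower, 0 higher and 3 did not pass; 15 passed adjusted over the list alone. Against all genes the list median was −1.97 (limma camera adjusted p = 1.85e-08; adjusted p = 0.276 with an estimated correlation), and the score difference was −1.99 (exact permutation p = 0.0159). Of the T cell, B cell and border myeloid genes, Nkg7, a granule protein of cytotoxic lymphocytes, fell from 14.7 ± 12.7 to 1.07 ± 0.672 TPM and the protease Gzmb from 3.29 ± 2.35 to 0.308 ± 0.445 TPM. In that list 8 of 16 tested members, Ly6c2 included, were lower and 0 higher, 8 did not pass, and 12 passed adjusted over the list alone. Its median relative to all genes was −1.21 (limma camera adjusted p = 0.000972; adjusted p = 0.459 with an estimated correlation), and the score difference was −1.24 (exact permutation p = 0.0238). Scores of the groups overlapped in both lists. For antigen presentation miR-130a library 15 scored −0.050, above control library 5 at −0.069. For the lymphoid list it scored 0.15, above control libraries 4 and 5 at −0.17 and −0.090. Control libraries 7 and 9 had the highest scores of both lists, 1.78 and 2.13 for antigen presentation and 1.18 and 1.59 for the lymphoid list. Without them, 7 antigen presentation genes were lower (limma camera adjusted p = 0.000476; score, exact permutation p = 0.0536), and 5 of the lymphoid list, which no longer passed (limma camera adjusted p = 0.0895; score, exact permutation p = 0.0893).

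Markers of reactive astrocytes were lower, while general astrocyte markers did not pass camera as a group. The intermediate filaments Gfap and Vim fell from 396 ± 111 to 114 ± 43.2 TPM and from 157 ± 67.2 to 40.4 ± 8.47 TPM, and Osmr, the oncostatin M receptor, from 4.69 ± 1.32 to 1.39 ± 0.339 TPM (SD, n = 5 each). Of 16 tested reactive astrocyte genes, 14 were lower and 0 higher, 2 did not pass, and 16 passed adjusted over the list alone. Its median relative to all genes was −1.01 (limma camera adjusted p = 5.94e-10; adjusted p = 0.222 with an estimated correlation), and the scores did not overlap between the groups (exact permutation p = 0.00794, the smallest possible). Control libraries 7 and 9 had the highest scores, 1.05 and 0.97, and without them 11 genes were lower. Of 15 general astrocyte markers, 1 was lower, the pump subunit Atp1b2 at 303 ± 54.9 and 213 ± 34.2 TPM, 0 were higher, and 0 passed adjusted over the list alone. The call of Atp1b2 was lost without any of 8 of the 10 libraries in turn (limma adjusted p up to 0.0976). The transcription factor Sox9 was at 15.5 ± 1.96 and 11.4 ± 2.00 TPM and the glutamate transporter Slc1a3 at 287 ± 25.6 and 239 ± 17.9 TPM, both without passing. The list had a median relative to all genes of −0.17 and did not pass camera (limma camera adjusted p = 0.264; adjusted p = 0.656 with an estimated correlation), whereas fry passed downward (adjusted p = 0.0458) and the score had an exact permutation p of 0.0317 (0.0511 adjusted over the lists).

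Vascular markers were lower. The endothelial adhesion molecules Pecam1 and Cdh5 fell from 20.7 ± 2.20 to 12.4 ± 1.30 TPM and from 10.8 ± 0.781 to 6.46 ± 0.897 TPM, and the efflux transporter Abcb1a from 15.7 ± 1.17 to 10.3 ± 1.92 TPM (SD, n = 5 each). Of 15 endothelial genes, 9 were lower, 0 higher and 6 did not pass; 10 passed adjusted over the list alone (median relative to all genes −0.34; limma camera adjusted p = 0.000283; adjusted p = 0.258 with an estimated correlation). Of 16 mural cell and fibroblast genes, 9 were lower, 0 higher and 7 did not pass; 14 passed adjusted over the list alone (median relative to all genes −0.60; limma camera adjusted p = 3.41e-06; adjusted p = 0.222 with an estimated correlation). The matrix proteins Fn1 and Vtn fell from 25.5 ± 3.39 to 13.8 ± 2.44 TPM and from 128 ± 12.2 to 73.6 ± 12.6 TPM, and the pericyte receptor Pdgfrb from 12.1 ± 0.569 to 7.68 ± 1.20 TPM. When control libraries 7 and 9 were left out, 6 endothelial and 4 mural genes were lower.

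In the oligodendrocyte lineage no member passed the limma threshold over all genes. Of 15 oligodendrocyte and myelin genes, 0 were lower or higher and 0 passed adjusted over the list alone (median relative to all genes −0.16; limma camera adjusted p = 0.408; adjusted p = 0.817 with an estimated correlation). Their lowest p-values belonged to the myelin regulator Myrf at 16.2 ± 4.18 and 9.78 ± 4.04 TPM, transferrin (Trf) at 386 ± 108 and 246 ± 107 TPM, and the myelin enzyme Cnp at 243 ± 46.1 and 180 ± 54.9 TPM (SD, n = 5 each). Of 12 precursor genes, 0 were lower or higher and 0 passed adjusted over the list alone (median relative to all genes −0.19; limma camera adjusted p = 0.143; adjusted p = 0.541 with an estimated correlation). The precursor score was nevertheless lower in every miR-130a library than in every control (difference −0.26; exact permutation p = 0.00794, the smallest possible). C1ql1 was at 8.72 ± 0.393 and 6.50 ± 1.25 TPM, the receptor Gpr17 at 17.2 ± 3.78 and 12.2 ± 1.67 TPM, and the lineage factor Olig2 at 18.4 ± 2.89 and 13.9 ± 2.03 TPM. Without control libraries 7 and 9, 2 precursor genes were lower, Gpr17 and Olig2 (limma adjusted p = 0.0402 and 0.0482).

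The inhibitory neuron list was higher by camera and by its scores but not by fry. Among its members besides Cort, somatostatin (Sst) rose from 645 ± 30.4 to 1065 ± 182 TPM and neuropeptide Y (Npy) from 251 ± 19.2 to 334 ± 42.8 TPM (SD, n = 5 each). Of 17 inhibitory neuron genes, 5 were higher, 0 lower and 12 did not pass; 5 passed adjusted over the list alone. Relative to all genes, the median was 0.28 (limma camera adjusted p = 7.74e-06; adjusted p = 0.223 with an estimated correlation), the direction test of fry did not pass (adjusted p = 0.0774), and every miR-130a score lay above every control score (exact permutation p = 0.00794, the smallest possible). Control library 9 had the lowest score, −0.49. Without control libraries 7 and 9, 3 genes were higher, and Npy missed the threshold (limma adjusted p = 0.0606; log2 fold change 0.34 against 0.40 with all libraries), as it did without any of 5 single libraries (up to 0.0659). Of 15 excitatory neuron genes, 0 were lower or higher and 0 passed adjusted over the list alone, with a median of −0.06 (0.04 relative to all genes). Camera pointed up and fry down in that list, neither passing (limma camera adjusted p = 0.552; adjusted p = 0.817 with an estimated correlation; fry adjusted p = 0.753). The cortical factors Neurod6, Neurod2 and Fezf2 were at 77.4 ± 14.2 and 101 ± 15.4 TPM, 48.4 ± 8.0 and 38.6 ± 3.85 TPM, and 29.4 ± 6.29 and 35.7 ± 3.84 TPM.

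Of 21 immediate early genes, 2 were higher, 1 was lower and 18 did not pass; 4 passed adjusted over the list alone. The neurotrophin Bdnf rose from 9.93 ± 1.24 to 14.4 ± 2.61 TPM, the nuclear receptor Nr4a3 rose from 5.88 ± 0.718 to 10.2 ± 3.43 TPM, and the factor Klf4 fell from 3.52 ± 0.50 to 2.05 ± 0.584 TPM (SD, n = 5 each). These 3 calls were lost without control libraries 7 and 9 (limma adjusted p = 0.0738, 0.0686 and 0.0865), with log2 fold changes of 0.43, 0.67 and −0.49 against 0.49, 0.66 and −0.58 with all libraries, and on leaving out 5, 5 and 4 of the 10 libraries in turn (up to 0.0803, 0.0825 and 0.0775). The list did not pass (median relative to all genes 0.20; limma camera adjusted p = 0.0588; adjusted p = 0.656 with an estimated correlation). Without control libraries 7 and 9 it passed camera (limma camera adjusted p = 0.0247), with 0 genes lower or higher. Its score did not differ there (exact permutation p = 0.714). Of 26 synapse genes, 0 were lower or higher and 0 passed adjusted over the list alone. The glutamate receptor subunit Gria1 was at 96.5 ± 19.4 and 126 ± 11.2 TPM and the scaffold Shank3 at 87.2 ± 19.4 and 66.1 ± 7.48 TPM. The synapse list nevertheless passed camera with a median relative to all genes of 0.12 (limma camera adjusted p = 0.0449; adjusted p = 0.656 with an estimated correlation), and it did not pass without control libraries 7 and 9 (limma camera adjusted p = 0.878), where 5 of its genes were lower and 0 higher, at a median of −0.10 or 0.047 relative to all genes.

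In monoamine and neuropeptide signalling, 3 of 22 tested genes were higher, 1 was lower and 18 did not pass; 4 passed adjusted over the list alone. The tachykinin precursor Tac1 rose from 17.3 ± 3.07 to 28.6 ± 2.03 TPM and Crhbp, which binds corticotropin-releasing hormone, rose from 21.5 ± 2.82 to 39.2 ± 9.65 TPM (SD, n = 5 each). The adrenergic receptor Adra2a fell from 6.08 ± 0.978 to 3.93 ± 0.584 TPM, a call lost without any of 6 of the 10 libraries in turn (limma adjusted p up to 0.0646). The list's median relative to all genes was 0.16 (limma camera adjusted p = 0.0197; adjusted p = 0.433 with an estimated correlation). Without control libraries 7 and 9 the list did not pass (limma camera adjusted p = 0.185), with 3 genes lower and 2 higher. Its median, not taken relative to all genes, was then −0.067, against 0.069 with all libraries. Of 16 tested glucocorticoid response genes, 1 was lower, the kinase Sgk1 (37.2 ± 5.15 to 27.0 ± 1.75 TPM), 0 were higher, and 1 passed adjusted over the list alone. Pdk4 was at 6.16 ± 1.62 and 4.08 ± 1.21 TPM and Ddit4 at 26.0 ± 2.89 and 31.8 ± 5.76 TPM. That list did not pass, with a median of −0.04, a camera direction up and a fry direction down (limma camera adjusted p = 0.742; adjusted p = 0.817 with an estimated correlation; fry adjusted p = 0.16).

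Genes of mitochondrial respiration were higher. Among nuclear genes, the cytochrome oxidase subunit Cox5a rose from 304 ± 31.5 to 465 ± 58.1 TPM, the complex I subunit Ndufb3 from 114 ± 16.9 to 173 ± 25 TPM, and cytochrome c (Cycs) from 41.7 ± 3.33 to 55.5 ± 4.61 TPM (SD, n = 5 each). Of 23 nuclear oxidative phosphorylation genes, 8 were higher, 0 lower and 15 did not pass; 14 passed adjusted over the list alone. Relative to all genes, the median was 0.43 (limma camera adjusted p = 1.4e-12; adjusted p = 0.0763 with an estimated correlation), and the scores did not overlap between the groups (difference 0.33; exact permutation p = 0.00794, the smallest possible). In the absence of control libraries 7 and 9, 12 of these genes were higher. Whether Cycs or other nuclear members share reads with processed copies was not tested. Of 13 mitochondrially encoded genes, 8 were higher, 0 lower and 5 did not pass; 9 passed adjusted over the list alone. The complex I subunits mt-Nd6, mt-Nd4l and mt-Nd4 rose from 3924 ± 464 to 5756 ± 297 TPM, from 3731 ± 1052 to 7059 ± 1591 TPM and from 6390 ± 671 to 9225 ± 1266 TPM. The oxidase subunit mt-Co2 rose from 159 ± 71.8 to 383 ± 154 TPM, a call lost without any of 7 of the 10 libraries in turn (limma adjusted p up to 0.107) and without control libraries 7 and 9 together (0.101). Its log2 fold change was 1.28 with all libraries, 1.08 to 1.36 in those 7 cases and 1.11 without control libraries 7 and 9. Reads of these genes may be shared with nuclear copies. Quantile normalization ended the calls of mt-Nd4l and mt-Nd4 (limma adjusted p = 0.0693 and 0.285), and mt-Nd4 also missed the threshold without control library 3, control library 7 or miR-130a library 14 (0.0545, 0.0525 and 0.0530). The median relative to all genes was 0.59 (limma camera adjusted p = 6.07e-09; adjusted p = 0.0763 with an estimated correlation), and under quantile normalization it was 0.21, which did not pass (limma camera adjusted p = 0.0735).

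Of 25 cytosolic ribosome genes, 3 were lower, 0 higher and 22 did not pass; 3 passed adjusted over the list alone. Rplp0 fell from 484 ± 57.3 to 331 ± 46.1 TPM, Rpl4 from 735 ± 24.4 to 590 ± 28.1 TPM and Rpl10 from 393 ± 42.6 to 281 ± 43.3 TPM (SD, n = 5 each). These 3 calls were lost under median-ratio scaling (limma adjusted p = 0.0752, 0.211 and 0.106), and ribosomal genes have many processed copies with which reads may be shared. The list as a group did not pass: its mean was −0.10, its median −0.07 or 0.02 relative to all genes, and camera pointed down (limma camera adjusted p = 0.699; adjusted p = 0.915 with an estimated correlation). Camera pointed up and passed without control libraries 7 and 9 (median relative to all genes 0.23; limma camera adjusted p = 0.00843). Of 17 tested stress and DNA damage genes, 3 were lower, 0 higher and 14 did not pass; 4 passed adjusted over the list alone. Heme oxygenase (Hmox1) fell from 15.2 ± 3.71 to 6.06 ± 1.32 TPM, the stress sensor Sesn2 from 11 ± 1.74 to 7.06 ± 0.595 TPM and the factor Atf3 from 6.42 ± 2.81 to 1.74 ± 1.10 TPM, the last without passing when control libraries 7 and 9 were left out (limma adjusted p = 0.0631; log2 fold change −1.13 against −1.43). This list did not pass camera (median relative to all genes −0.10; limma camera adjusted p = 0.0564; adjusted p = 0.258 with an estimated correlation), although its scores did not overlap between the groups (exact permutation p = 0.00794, the smallest possible).

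Of 22 tested genes reported elsewhere as targets of miR-130a-3p, 6 were lower, 1 was higher and 15 did not pass; 8 passed adjusted over the list alone. Csf1 (ENSMUSG00000014599), the growth factor of microglia and macrophages, fell from 24.4 ± 2.89 to 10.2 ± 1.46 TPM (log2 fold change −1.18, limma adjusted p = 0.000503), and its 3′ UTR held 3 sites. The TGF-beta receptor Tgfbr2 fell from 17.7 ± 3.82 to 6.60 ± 0.674 TPM with 1 site and the cholesterol transporter Abca1 from 10.6 ± 1.97 to 3.84 ± 0.845 TPM with 2 sites (SD, n = 5 each). The BMP receptor Acvr1 fell from 19.8 ± 2.49 to 13.1 ± 1.73 TPM with 2 sites. Irf1, an interferon regulatory factor, fell from 33.9 ± 18.6 to 9.30 ± 6.0 TPM and Tac1 rose, both with 0 sites in the UTR searched. Csf1 is also a member of the activated microglial list, and the fall of these targets was not separated from that of the immune lists. Against all genes the list median was −0.15 (limma camera adjusted p = 0.0408; adjusted p = 0.524 with an estimated correlation), and every miR-130a score lay below every control score (difference −0.37; exact permutation p = 0.00794, the smallest possible). The camera call was lost without control library 5 (adjusted p = 0.0650), control library 9 (0.0666), miR-130a library 13 (0.0542), miR-130a library 17 (0.151) or control libraries 7 and 9 together (0.0844).

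Across the transcriptome, genes with a miR-130a-3p site were slightly lower than genes without one. Of 13307 genes searched, 2228 had a site, and their score was lower by a difference of −0.055 log2 units against site-free genes of similar UTR length (1-sided exact permutation p = 0.0317; 2-sided 0.0635). Among 50 shuffled heptamers 0 gave a value as low; theirs ranged from −0.046 to 0.066. The 332 genes with an 8mer differed by −0.11 (1-sided exact permutation p = 0.0357; 2-sided 0.0714) and the 387 with at least 2 sites by −0.11 (1-sided exact permutation p = 0.0198; 2-sided 0.0397). Matched on UTR length and AT content, an alternative added after the data were seen, the 2228 site genes differed by −0.067 (1-sided exact permutation p = 0.00794; 2-sided 0.0159). Without matching on UTR length, whose median was 2631 bases in site genes and 1197 in site-free genes, 13.8% and 12.7% were lower in limma and 0.987% and 2.40% higher. The difference was −0.031 without miR-130a library 17, and the 1-sided exact permutation p was 0.0635 without control library 3 or 5 or without miR-130a library 13, 15 or 17.

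**Figure D3:**
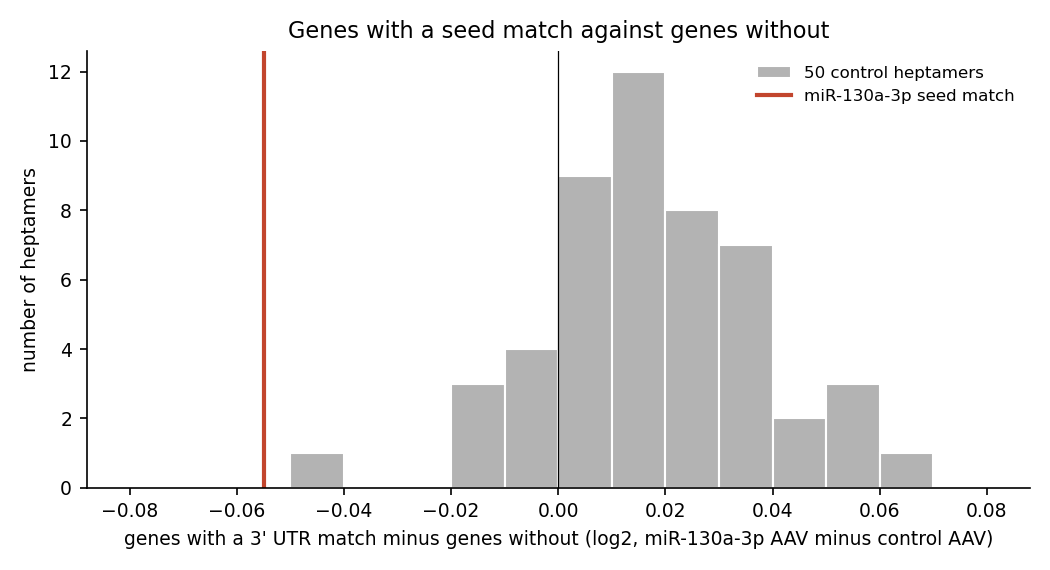
Histogram of the difference in log2 units between genes with and without a site (miR-130a minus control, matched on UTR length) for 50 shuffled heptamers, with a line at the miR-130a-3p site; the vertical axis counts heptamers. The miR-130a-3p value of −0.055 lies below the lowest shuffled heptamer at −0.046.

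The remaining lists concerned the microRNA machinery and tissue next to the punch. Of 12 microRNA machinery genes, 1 was lower, Ago1 (18.5 ± 2.18 to 13.4 ± 1.94 TPM; SD, n = 5 each), 0 were higher, and 1 passed adjusted over the list alone. That call was lost without any of 7 of the 10 libraries in turn (limma adjusted p up to 0.0805). Xpo5 was at 18.3 ± 2.69 and 15.3 ± 0.978 TPM and Ago2 at 10.3 ± 2.30 and 8.53 ± 0.688 TPM, and the list did not pass (median relative to all genes −0.11; limma camera adjusted p = 0.251; adjusted p = 0.702 with an estimated correlation). Of 12 tested striatum and claustrum genes, Tac1 was higher and Adora2a lower (4.17 ± 0.967 to 2.36 ± 0.707 TPM; lost without any of 8 single libraries, limma adjusted p up to 0.106), 10 did not pass, 2 passed adjusted over the list alone, and Drd1 was at 5.71 ± 2.22 and 7.05 ± 2.14 TPM. That list passed camera (median relative to all genes 0.23; limma camera adjusted p = 0.0320; adjusted p = 0.267 with an estimated correlation) but not without control libraries 7 and 9 (limma camera adjusted p = 0.104). Of 3 tested choroid plexus and ependyma genes, Foxj1 was lower (5.21 ± 0.865 to 2.70 ± 1.08 TPM; lost without any of 4 single libraries, limma adjusted p up to 0.0684), 0 were higher, and 2 passed adjusted over the list alone; Aqp1 was at 1.71 ± 1.26 and 0.460 ± 0.176 TPM and Rarres2 at 16.3 ± 5.63 and 11.7 ± 3.67 TPM (median relative to all genes −0.68; limma camera adjusted p = 0.109; adjusted p = 0.433 with an estimated correlation; score, exact permutation p = 0.00794). Of 6 blood genes, 1 was higher, 0 were lower and 1 passed adjusted over the list alone. Alas2 was at 2.90 ± 1.39 and 1.97 ± 0.851 TPM and the globin Hbb-bs, whose reads may be shared with its paralogs, at 479 ± 191 and 485 ± 106 TPM. The blood list did not pass, with a median of −0.00032 and a mean of 0.04 (limma camera adjusted p = 0.228; adjusted p = 0.656 with an estimated correlation). Without control libraries 7 and 9 its median was 0.38 and it passed camera (limma camera adjusted p = 0.00203). Its score did not pass there (exact permutation p = 0.161), and 1 gene was higher and 0 lower. Of 4 tested sex-linked genes, 0 were lower or higher and 0 passed adjusted over the list alone. Kdm5d was at 3.57 ± 0.762 and 3.03 ± 0.725 TPM, Ddx3y at 10.4 ± 3.16 and 12.3 ± 4.01 TPM and Uty at 2.53 ± 0.444 and 2.28 ± 0.775 TPM, with a camera direction up and a fry direction down (limma camera adjusted p = 0.589; adjusted p = 0.817 with an estimated correlation; fry adjusted p = 0.906).

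Over all 29 lists, 17 passed camera at the preset correlation, 17 passed fry and 17 passed the exact permutation test of their scores after adjustment over the lists. With an estimated correlation 0 passed limma's camera, where 6 had an unadjusted p under 0.05. Of 3145 annotation terms, 353 were lower and 85 higher at the preset correlation, and 0 passed with an estimated correlation, where 158 had an unadjusted p under 0.05. The lowest p among lower terms belonged to complement and coagulation cascades, in which 30 of 38 genes, Itgax and C1qc among them, were lower (camera adjusted p = 5.52e-11; adjusted p = 0.886 with an estimated correlation). It was followed by Staphylococcus aureus infection (26 of 34 genes, among them C1qc and C1qb), defense response (21 of 27, among them Stat6 and Tnfrsf1a), Epstein-Barr virus infection (73 of 171, among them Tlr2 and Oas1a) and graft-versus-host disease (17 of 23, among them H2-Q6 and H2-T22). The lowest p among higher terms belonged to oxidative phosphorylation, in which 45 of 120 genes were higher and 4 lower (camera adjusted p = 1.12e-23; adjusted p = 0.886 with an estimated correlation). The proton pump subunit Atp6v1d was among its higher genes and the pump subunit Tcirg1, found in osteoclasts and immune cells, among its lower ones. It was followed by respiratory chain complex I (21 of 50 genes), complex I assembly (14 of 47), both with Ndufs5 and Ndufa5, NADH dehydrogenase activity (10 of 25, with mt-Nd6 and Ndufa5) and thermogenesis (47 of 204 higher and 10 lower, with Cox5a higher). The number of terms past the threshold without control libraries 7 and 9 was 333.

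**Figure D4:**
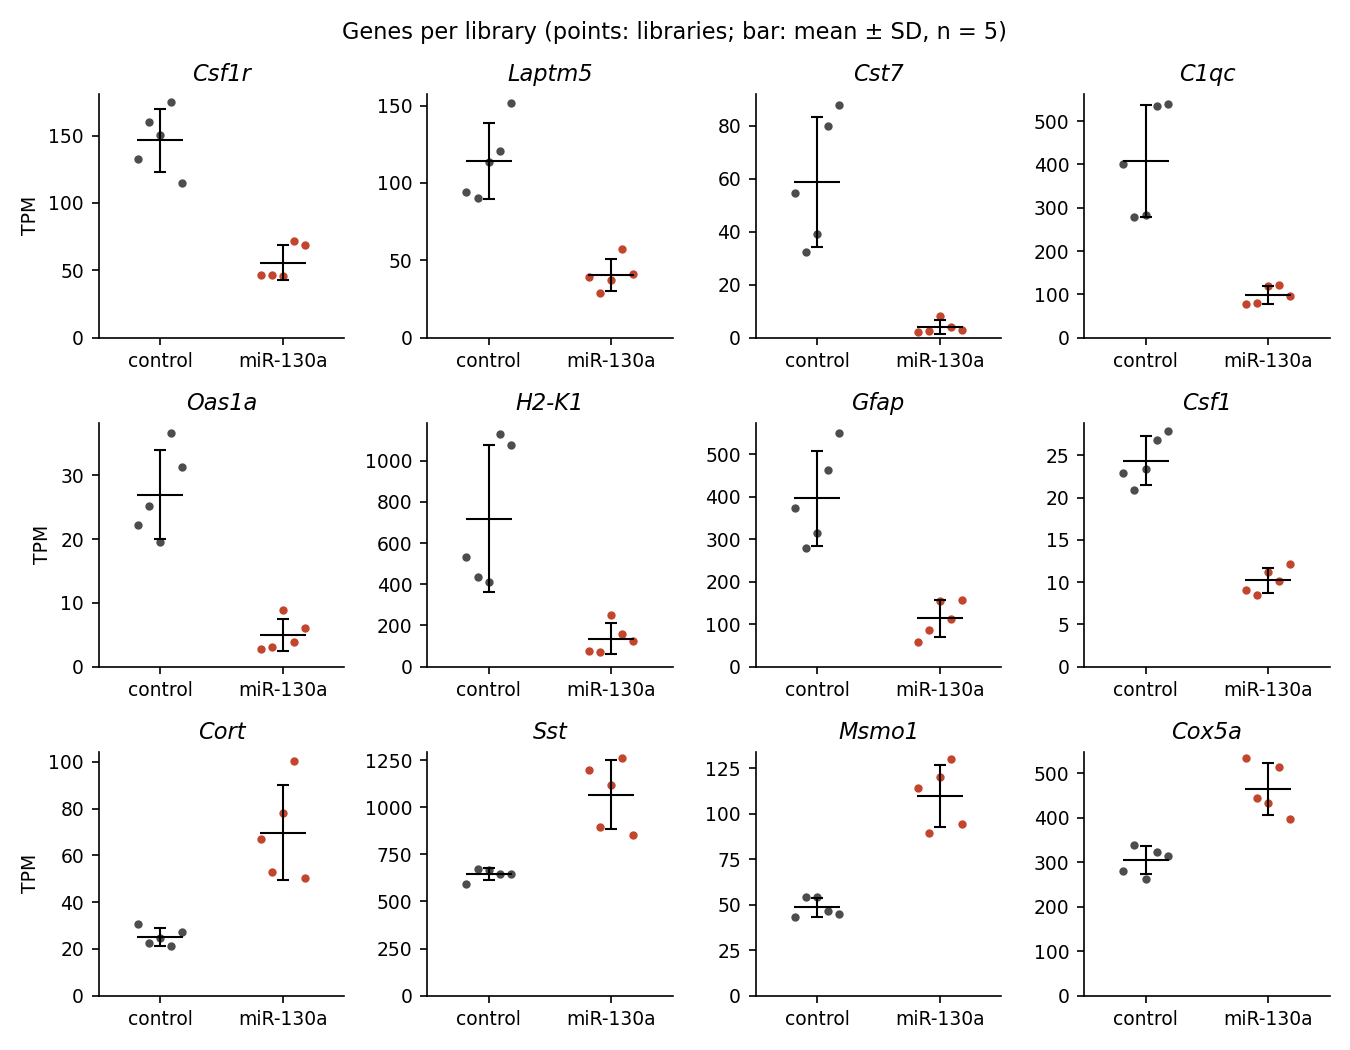
TPM per library for 12 of the named genes, each on its own linear axis from 0, with a point per library and bars for mean ± SD (n = 5). Csf1 lies at 24.4 ± 2.89 TPM in control and 10.2 ± 1.46 TPM in miR-130a libraries (SD, n = 5 each).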

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

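The tests of control libraries 7 and 9, of microglial state, of sites within the lists, of the neuron share and of the TPM scaling were chosen only after the results they bear on were seen. The 10 libraries can be split into 5 and 5 in 126 ways, of which 100 were drawn with the real one included. For the number of changed genes the splits argue against chance, though not against a cage or processing block that coincides with the group. There 1 of 100 splits, the real one, gave as many as 2110, and the highest of the others gave 131. For the number of annotation terms 1 of 100 splits, again the real one, gave as many as 438, but the highest of the others came to 418. That margin is narrow and 0 terms passed with an estimated correlation, so chance is not excluded there. For the number of gene lists past limma's camera at the preset correlation chance cannot be excluded, because 18 of 100 splits gave at least the real 17 and the highest of the others gave 21.

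The homeostatic and activated microglial, complement, interferon, NF-kB and reactive astrocyte lists were lower in the miR-130a group. The score ranges of 6 of these 6 lists stayed apart without control libraries 7 and 9. That could not decide their part, because ranges that lie apart with all libraries stay apart when controls are left out. The values still argue against these libraries as the whole source. Without them the 6 medians lay between −0.74 for NF-kB and cytokine genes and −1.46 for the interferon response. Fewer microglia of unchanged state would lower both microglial scores alike if all members came from microglia alone. The activated score fell by 0.58 log2 units more than the homeostatic one (exact permutation p = 0.00794, the smallest possible, n = 5 each). The cell origin of the members was not tested. Members also made in other cells could give such a gap, so it cannot decide whether microglial state changed. Control libraries 7 and 9 carried part of that gap: without them it was 0.35, with the lowest control at −0.064 and the highest miR-130a library at −0.097 (exact permutation p = 0.0179, the smallest possible with 3 controls). The tables argue against the TPM scaling as the source, because the 6 medians under quantile normalization lay between −0.81 for homeostatic microglia and −1.61 for the interferon response. Repression of each gene through sites of its own is argued against for most members, because 98 of the 108 lower genes had no site in the UTR searched; sites elsewhere were not searched. For the 10 with a site such repression cannot be told apart from other routes, as their share of 9.26% (exact 95% interval 4.53% to 16.4%) was not above the 10.8% expected from UTR length. For antigen presentation the part of control libraries 7 and 9 cannot be told apart from a group difference: without them the median was −1.47 against −2.07 with all libraries and 7 genes were still lower, but the score had an exact permutation p of 0.0536 on the 3 controls left. The same holds for the lymphoid list, with a median of −0.72 against −1.31 and an exact permutation p of 0.0893. A response of microglia or other cells to the overexpressed microRNA, through few direct targets or many, remains among the open explanations. Both groups were given an AAV, and no library came from mice without one. A fall of these lists in the miR-130a group therefore cannot be told apart from a raised level in the controls.

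Nuclear oxidative phosphorylation genes were higher in the miR-130a group. Short transcripts could not be decided as a source. Of 10000 random lists matched on expression and on the longest annotated transcript of each gene, 0% had a median as high as 0.33. The highest of them reached 0.29. Their typical median was 0.024, against −0.095 for all tested genes, so length and expression go with part of the rise. The lists did not reach all of it, but shorter forms in use were not matched. Their genes were also drawn without regard to correlation between members. A larger share of neurons cannot be told apart from a change within cells. The oxidative phosphorylation score rose by 0.38 more than the excitatory neuron score (exact permutation p = 0.0476, n = 5 each), but leaving out single libraries moved that p from 0.00794, without control library 9, to 0.0952, without control library 5 or miR-130a library 17. Without control libraries 7 and 9 that difference was 0.57 (exact permutation p = 0.0179, the smallest possible with 3 controls), 12 oxidative phosphorylation genes were higher, and the excitatory list had 2 of 15 genes lower, a lower score (exact permutation p = 0.0179) and a median of −0.22, but −0.069 relative to all genes, and did not pass camera (limma camera adjusted p = 0.443). The inhibitory neuron list was higher with all libraries (median 0.19), which goes with more neurons, but only 5 of its 17 genes passed. Its members Gad1 and Gad2, chosen after their values were seen, did not pass (limma adjusted p = 0.630 and 0.317). A response of metabolism to the overexpressed microRNA, which the design names, was not tested.

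Single libraries lay far from the other 4 of their group in 11 of 286 comparisons of 5 libraries, where chance gives about 14.3; the ratio of the gap to the group's range then exceeded 0.71. Among list scores this was miR-130a library 17, lowest for synapse (ratio 0.733), and control library 4, highest for the glucocorticoid response (0.813). Among increased genes it was miR-130a library 18, lowest for Ucma (0.711), miR-130a library 15, highest for Fabp7 (0.884) and for Spink8 (0.758), and control library 4, lowest for Spink8 (0.753) and for mt-Nd6 (0.733). Control library 9 was lowest for Shank3 (0.794) and for Sesn2 (0.713), miR-130a library 13 highest for Sesn2 (0.722), and miR-130a library 17 lowest for Acvr1 (0.798).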

How the results depend on the processing

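The alternatives without control libraries 7 and 9 and with protein-coding genes alone were chosen after seeing the data. Of 83 named genes past the threshold, 53 passed under each alternative that tested them, 23 were lost on leaving out at least 1 single library and 15 without control libraries 7 and 9. All lost calls kept their direction, at 76.9% to 111% of the reported log2 fold change on leaving out single libraries and at 57.8% to 111% without control libraries 7 and 9. Calls were also gained without these 2 libraries. Gpr17, Olig2, Neurod2, Shank3 and Xpo5 were then lower (limma adjusted p = 0.0402, 0.0482, 0.0148, 0.0124 and 0.0321). So were 3 general astrocyte and 3 microRNA machinery genes. The homeostatic, activated, complement, interferon, antigen presentation and nuclear oxidative phosphorylation lists kept their direction and passed under each alternative except camera with an estimated correlation. That setting left 0 of 29 lists and 0 terms past the threshold without moving the medians, because it allows for the correlation between members: homeostatic −0.87 (limma camera adjusted p = 0.0763), activated −1.21 (0.222), complement −1.53 (0.222), interferon −1.68 (0.223), antigen presentation −1.97 (0.276), reported targets −0.15 (0.524), mitochondrially encoded 0.59 (0.0763) and oxidative phosphorylation 0.43 (0.0763). Without a filter, where more genes are tested, 1302 genes passed, 1124 lower and 178 higher. Array weights gave 3840, 3144 lower and 696 higher. Quantile normalization gave 1046 lower and 1071 higher, median-ratio scaling 866 higher and protein-coding genes alone 563 higher. Leaving out single libraries gave 1254 to 3421 genes, 1108 to 2922 lower and 146 to 499 higher. Without control libraries 7 and 9, 11 list scores passed the exact permutation test after adjustment over the lists, with 3 controls left.

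The reported targets missed the camera threshold at −0.19 with a filter of 5 TPM, −0.12 under quantile normalization, −0.13 with array weights, −0.20 without control libraries 7 and 9 and −0.17 with protein-coding genes alone, and ranged from −0.19 to −0.10 on leaving out single libraries. The site comparison ranged from −0.068 to −0.031, and 5 of those 10 values missed the threshold. The mitochondrially encoded list missed it at 0.21 under quantile normalization. The test directions of lists and the fold directions of genes turned only for results that had not passed as reported. Without a filter these were the glucocorticoid list (−0.035) and choroid plexus (0.033), and under quantile normalization Kdm5d (0.023) and Uty (0.070). The camera direction of the ribosome list turned up at medians of 0.039 under median-ratio scaling, 0.051 with protein-coding genes and 0.23 without control libraries 7 and 9, where it passed. Fry took the opposite direction to camera for excitatory neurons (0.038), glucocorticoid (0.053) and sex-linked genes (0.090). Without control libraries 7 and 9, excitatory neurons (−0.069) and Drd1 (−0.026) turned, and for oligodendrocytes camera's direction turned while the median kept its sign (−0.069). The synapse and monoamine lists had passed camera as reported and kept its direction there. Their medians, not taken relative to all genes, turned from 0.027 to −0.10 and from 0.069 to −0.067. Leaving out single libraries gave ranges across 0 or a turned test for Hbb-bs (−0.11 to 0.26), oligodendrocytes (−0.31 to 0.031), excitatory neurons (−0.062 to 0.084), glucocorticoid (0.0070 to 0.094), the ribosome (−0.051 to 0.16) and sex-linked genes (−0.050 to 0.20). Apart from the number of genes or libraries, the cause was not tested. No paired analysis was possible because the groups share no replicate numbers. The depth of the libraries is unknown, so its limits cannot be given.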

Other observations

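The gene groups and genes in this part were chosen after their values were seen, except the sites and named genes already described. Several enzymes of cholesterol synthesis were higher in the miR-130a group. Besides Msmo1 and Hmgcs1, the squalene epoxidase Sqle rose from 37.1 ± 7.03 to 60.7 ± 11.7 TPM and Insig1, a sterol sensor of the same regulatory circuit, from 33.0 ± 4.07 to 58.9 ± 11.5 TPM (SD, n = 5 each). Of 22 genes of the term for cholesterol biosynthesis, 10 were higher and 0 lower (limma camera adjusted p = 6.44e-09; adjusted p = 0.886 with an estimated correlation), a term picked from the tested terms after its result was seen. The count was 11 under median-ratio scaling. The regulator Srebf2 was at 125 ± 31.9 and 129 ± 14.9 TPM and did not pass (limma adjusted p = 0.831).

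Lysosomal genes were lower beyond the microglial proteases. Psap, the precursor of the saposins, fell from 1699 ± 85.6 to 1029 ± 92.1 TPM and the lysosomal membrane protein Lamp1 from 431 ± 57.5 to 273 ± 20.1 TPM (SD, n = 5 each). Of 120 genes of the lysosome term, 49 were lower and 0 higher (limma camera adjusted p = 8.83e-09; adjusted p = 0.886 with an estimated correlation), a term also picked after its result was seen. Under median-ratio scaling 38 were lower and 2 higher. Of the interneuron genes, Nos1, the neuronal nitric oxide synthase, rose from 6.52 ± 1.03 to 9.62 ± 1.17 TPM and the peptide Vip from 36.4 ± 2.5 to 47.7 ± 6.31 TPM, while the GABA-synthesizing enzymes Gad1 and Gad2 were at 170 ± 66.3 and 183 ± 13.7 TPM and at 25.4 ± 2.85 and 31.4 ± 7.44 TPM without passing (limma adjusted p = 0.630 and 0.317).

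Immunoglobulin genes, 267 in the table, added to between 536 and 19621 TPM in control and between 306 and 2322 TPM in miR-130a libraries (exact permutation p = 0.127), with the highest sums, 11388 and 19621 TPM, in control libraries 7 and 9. T cell receptor genes, 226 in the table, added to 67.0 to 189 TPM and 50.9 to 80.8 TPM (exact permutation p = 0.0397), again highest in control libraries 7 and 9 (157 and 189 TPM), while control libraries 4 and 5 (67.0 and 77.1 TPM) lay inside the miR-130a range. Gm45665, a processed pseudogene whose reads may belong to its parent gene, was listed at 0 in 4 controls and at 62.1 TPM in control library 9, against 60.9 to 255 TPM in the miR-130a libraries (limma adjusted p = 0.00508). For this rise and that of LINC03051, vector sequence and genotype were not tested as a source. Among the 332 genes with an 8mer, 55 were lower and 3 higher in limma. Among them were Cd151, a tetraspanin, which fell from 41.3 ± 4.51 to 22.9 ± 2.01 TPM with 2 such sites, and Psap with 1.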
